A study of Homo sapiens and Drosophila melanogaster
Homo sapiens with 12 samples.

How the data were processed

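The measurement was MARGI, a sequencing assay for RNA attached to chromatin in which a linker joins an RNA fragment to nearby DNA inside crosslinked nuclear material, and each chimeric fragment is read from both ends. Per the labels, the first read is the RNA end and the second read is the DNA end. The cells were H9, a human embryonic stem cell line grown on matrigel in Essential 8 medium, and HEK, a human embryonic kidney cell line grown in DMEM with serum. Each line was taken through pxMARGI, in which formaldehyde-crosslinked chromatin is digested overnight with the enzyme HaeIII across the whole genome, and through diMARGI, in which chromatin crosslinked with formaldehyde and DSG is sonicated and its soluble fraction alone is carried on.

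Of the 12 samples, 3 were H9 pxMARGI, 2 were H9 diMARGI, 4 were HEK pxMARGI and 2 were HEK diMARGI, and 1 mixed HEK and Drosophila cells. The mixed sample served, per the labels, to count chimeras between species and was not used here. The titles give 2 replicates for each pxMARGI group and 1 for each diMARGI group, and number the further samples within a replicate.

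The authors deposited 4 tables, 1 for each line and protocol, each with the same 40849 genes in 43 classes, of which 0 are protein-coding. Per the file headers, each deposited table holds a count of RNA-end reads, a count of DNA-end reads, a p-value and a q-value for every gene. The counts are whole numbers with no normalization. The samples of a group had been pooled, so no comparison has a replicate. The submitters' processing notes name the GRCh38 genome build and FastQC. The aligner, the gene annotation, the counting rule and its use of strand are not given in the sources used here.

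The table names give the line and a protocol letter. The sample descriptions, however, name a HEK table for all 5 H9 samples and an H9 table for 5 of the 6 pooled HEK samples, while the sixth, a HEK pxMARGI sample by title, names the HEK diMARGI table. In 2 samples, 1 H9 diMARGI and 1 HEK pxMARGI by title, the protocol entry names the other protocol. The descriptions name the table of HEK pxMARGI 4 times, of HEK diMARGI 2 times, of H9 pxMARGI 3 times and of H9 diMARGI 2 times, which are the sizes of those groups by title, as they would be had the entries been made in another sample order. Samples were grouped by title, which matches the design text, and tables were assigned to lines by their own names. A swap of the lines would reverse every comparison of H9 with HEK and leave the comparisons of protocols in place under exchanged line names.

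The authors' p-values were computed per table and test the RNA-end count of a gene within its own table. Per the values that could be inverted, a deposited p-value is the upper tail of a Poisson distribution whose mean is a table constant multiplied by a fixed weight per gene. P-values outside the limits given next were not checked. The mean was recovered by inverting that tail for p-values between 1e-10 and 0.999, which gave an expected count for 30482 genes. The ratio of the recovered means between tables was constant within a tolerance of 0.001 for 100% of the genes compared. In simulated data, the inversion returned 1999 of 1999 known means within 0.001. How the authors set the weights is not given in the sources used here; across 11611 genes the weight followed the RefSeq gene span with a Spearman rho of 0.896.

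For a comparison of 2 tables, each gene's share of all RNA-end reads was divided by its share in the other table. The 95% interval of the ratio came from an exact conditional binomial (Clopper-Pearson) interval. A gene counted as higher when the table in which it was higher had at least 50 reads, the ratio reached 4-fold after adding a pseudocount of 0.5 reads, and the interval left out 1. The same 50 reads are a larger share of a shallower table, so a gene enters more readily as higher in the deeper one. Folds in the text are ratios without the pseudocount. A fold against a table with 0 reads was computed against a floor of 3 reads and is given as a lower bound. Shares of reads in a class carry exact Clopper-Pearson intervals at 95%. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only, and they compare the pools, not the conditions.

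Depth was 244809 RNA-end reads over genes in H9 pxMARGI, 43048 in H9 diMARGI, 364119 in HEK pxMARGI and 236995 in HEK diMARGI. The floor of 3 reads stood at 1.23, 6.97, 0.824 and 1.27 reads per 100000 in the same order.

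The genes named in the text followed a rule set before the data were examined, except for MT-TC, MT-TW, RPS10L, RPL4P4, RPL13P12, ESRG, LINC00678, MIR302C, MIR302D and MIR92A1, which were chosen after their values were seen. A gene that the rule named in 1 comparison could be given in others. The rule took the 10 genes with the most RNA-end reads in each table, the 10 genes with the largest ratio in each direction of each comparison among genes with 50 reads in the higher table, up to 4 members with the most reads from each of 14 gene lists, and the 10 genes with the smallest largest q-value among those past the authors' threshold in all 4 tables. The lists were spliceosomal snRNAs, nuclear lncRNAs, snoRNA host genes, snoRNAs, replication-dependent histones, mitochondrial transcripts, cytoplasmic small RNAs, ribosomal protein mRNAs, housekeeping mRNAs, pluripotency genes, HEK293-type genes, early lineage genes, 7SK-type and RNase RNAs, and imprinted non-coding RNAs. List members were counted at 2-fold or more, and the median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean reads. The mean was that of the 2 tables that form the ratio, and the draws could include the list's own members. A percentile thus ranks a list among genes of like mean reads. It does not measure how far the list lies from equal shares. Some genes stand in several lists and some names have 2 entries, so the lists overlap.

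The comparison was tested on simulated counts in which 200 genes were changed by known folds. Genes changed 8-fold were called in 61 of 62 cases for the H9 protocols, 100 of 100 for the HEK protocols, 100 of 100 for the lines in pxMARGI and 58 of 61 for the lines in diMARGI, among 219, 461, 1060 and 199 genes with 50 reads. Genes changed 2-fold, below the threshold, were called in 5 of 62, 0 of 99, 0 of 100 and 2 of 44 cases. Of the unchanged genes, 0 were called in each comparison, and the intervals held the true fold for 98.2%, 95.9%, 94.0% and 96.0% of genes. These values check the calculation under counting error only. They give no rate of false calls in the deposited tables, because PCR copies, differences between samples and shifts in composition between protocols were not tested.

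The alternatives were scaling by edgeR's TMM factors and by DESeq2's median of ratios, totals without mitochondrial and ribosomal RNA genes or without the 10 largest genes, minimums of 10, 0 and 200 reads, a pseudocount of 5, a 2-fold threshold, and q-value thresholds of 0.01, 0.001 and 0.1 with Benjamini-Hochberg values recomputed from the deposited p-values. Scaling by the recovered expected count, leaving out 389 entries that repeat another entry's counts, setting genes at 0 reads to the floor of 3 reads, asking for a whole interval beyond 4-fold, and taking RMRP and RPPH1 out of the nuclear lncRNA list were added after seeing the data. Reads on overlapping genes, antisense partners and near-identical copies such as the 7SL, U1, 5S rRNA and Y RNA families are uncertain, because the counting rule is unknown. Gene coordinates are those of RefSeq on GRCh38.p14, in which 15930 of the 40849 genes were matched by symbol.

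The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.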

Results

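RNA ends from pxMARGI and diMARGI, assays aimed at RNA attached to chromatin, were counted gene by gene in H9 embryonic stem cells and HEK kidney-derived cells. Whether a given RNA end came from RNA attached to chromatin was not tested. Each of the 4 combinations was a single pooled table of non-coding genes and pseudogenes, without replicates, so that differences are given with counting intervals and no p-value between groups. The tables held 244809 RNA-end reads in H9 pxMARGI, 43048 in H9 diMARGI, 364119 in HEK pxMARGI and 236995 in HEK diMARGI. RNA-end reads fell on 26586 genes in H9 pxMARGI, 2369 in H9 diMARGI, 27377 in HEK pxMARGI and 5037 in HEK diMARGI. The 10 genes with the most reads took 2.47% and 2.51% of RNA ends in H9 and HEK pxMARGI, against 58.5% and 60.7% in diMARGI. Per the design text, pxMARGI is meant to take in passive and direct contacts alike, while diMARGI aims at RNA held to chromatin by proteins.

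The classes of RNA were compared first, to show what each protocol recovered. Mitochondrial rRNA, the rRNA of the organelle's own ribosomes, made up 18.4% of RNA ends in H9 diMARGI (95% interval 18.001 to 18.7) and 35.6% in HEK diMARGI (35.5 to 35.8), against 0.491% and 0.457% in pxMARGI. The snRNAs, which form the core of the spliceosome, took 7.14% and 8.31% in H9 and HEK diMARGI against 0.580% and 0.930% in pxMARGI. The snoRNAs and scaRNAs, guides of RNA modification, took 3.94% and 7.82% against 0.542% and 0.505%. As a share, the lincRNAs went the other way, with 3.28% and 9.60% of RNA ends in diMARGI and 25.6% and 24.6% in pxMARGI, as did antisense RNAs with 6.07% and 3.55% against 23.5% and 22.9%. Over the recovered expected count, lincRNAs in HEK stood at 3.11 times in diMARGI against 1.03 in pxMARGI and antisense RNAs at 1.39 against 1.21. All genes with an expected count stood at 4.53 against 1.14 in HEK, so both classes rose less than all genes together. In H9 the lincRNAs stood at 0.451 against 1.04 and the antisense RNAs at 1.02 against 1.21, with all genes at 2.48 against 1.11. Of the 22757 lincRNA reads in HEK diMARGI, XIST had 11720 and RMRP, also listed as a ribozyme, 3991. Processed pseudogenes held 0.948% and 0.701% of diMARGI RNA ends and 19.8% and 20.9% of those in pxMARGI. The entries annotated as miRNA took 25.3% of H9 and 10.6% of HEK diMARGI RNA ends. That class includes RN7SL2, a gene of the 7SL RNA of the signal recognition particle, and AL353644.10, which alone had 6308 reads in H9 diMARGI, so the share is not one of mature miRNAs.

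**Figure D1:**
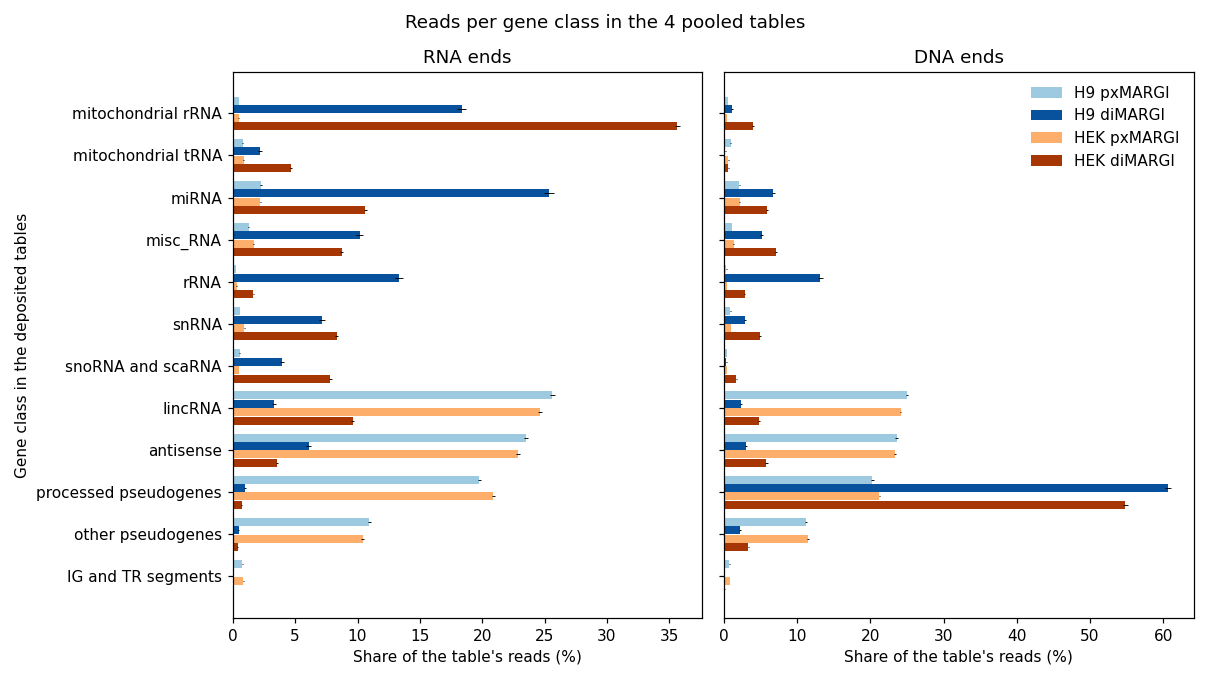
Share of RNA-end reads by RNA class in the 4 pooled tables, in percent of all RNA-end reads over genes, with exact 95% binomial intervals. Mitochondrial rRNA stood at 18.4% and 35.6% in H9 and HEK diMARGI and below 0.5% in both pxMARGI tables.

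Within each table, the authors' deposited q-value marks genes with more RNA ends than their expected count. MT-RNR1, the smaller mitochondrial rRNA, had a q-value of 0 in all 4 of the authors' deposited tables, with 188 and 414 reads in H9 and HEK pxMARGI and 2358 and 25511 in diMARGI. The mitochondrial tRNA genes MT-TP, MT-TF, MT-TS2, MT-TY and MT-TL2 were at 0 in the 4 authors' deposited tables as well, as were the antisense gene RP11-1348G14.8 and MTATP6P1, a nuclear copy of a mitochondrial gene. MT-TL1 and MT-TH followed with a largest q-value of 2.39e-15 in the authors' deposited tables, a value shared with MT-TC. In all, 59 genes passed a q-value of 0.05 in each of the 4 tables, against 0.258 for independent lists, among them 15 mitochondrial tRNAs, 2 mitochondrial rRNAs, 13 snoRNAs or scaRNAs, 12 antisense RNAs, 4 entries annotated as miRNA, 4 rRNA entries and 0 snRNAs. The value of 0.258 spreads calls over all 40849 genes, of which 2369 and 5037 had RNA ends in H9 and HEK diMARGI. An excess over it therefore follows in part from which genes have reads. The mitochondrial classes also had many DNA ends in pxMARGI. Mitochondrial tRNA had 1920 RNA ends and 2363 DNA ends in H9, and 3223 and 2567 in HEK. Mitochondrial rRNA had 1201 and 1480 in H9, and 1665 and 1662 in HEK. The recovered mean has a fixed weight per gene and does not use the DNA ends of a table. A pass therefore does not separate more RNA from more copies of a sequence.

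Genes past the authors' threshold of 0.05 numbered 4149 in H9 pxMARGI, 728 in H9 diMARGI, 5643 in HEK pxMARGI and 1032 in HEK diMARGI. Their median was 18, 6, 22 and 10 reads in the same order. The lines shared 2431 such genes in pxMARGI, against 573 for independent lists, and 493 in diMARGI, against 18.4. Among genes with 50 reads in both tables, the lines shared 370 in pxMARGI against 331 for independent lists, and in diMARGI 56 of 56, where every gene passed in both tables and the comparison with independent lists says nothing. The protocols shared 116 in H9, against 73.9, and 198 in HEK, against 143. Among genes with 50 reads in both tables, the protocols shared 4 in H9 and 25 in HEK, equal to the numbers for independent lists. Every such gene passed in diMARGI, so that comparison says nothing, and the same held for pairs crossing line and protocol. Across genes with a read in either table, the Spearman rho of RNA-end reads between H9 and HEK was 0.587 in pxMARGI and 0.0912 in diMARGI. Between the protocols it was -0.0464 in H9 and -0.0264 in HEK. Among genes with 50 reads in either table, rho was 0.430 and 0.206 between the lines in pxMARGI and diMARGI. Between the protocols it was then -0.245 in H9 and -0.186 in HEK. Crossing both line and protocol gave 165 shared genes against 105 for H9 pxMARGI with HEK diMARGI and 129 against 101 for H9 diMARGI with HEK pxMARGI, with rho values of -0.0344 and -0.0594. With 50 reads in either table these rho values were -0.437 and -0.0950. Genes are not independent replicates, and these values describe the tables.

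In H9, diMARGI was set against pxMARGI to ask which RNAs made up a larger share of its reads. The 7SL gene RN7SL1 (chromosome 14, 49586580 to 49586878) had 1765 reads in diMARGI and 2 in pxMARGI, 5019-fold more as a share (95% interval 1387 to 41473). RNVU1-7, a variant gene of the U1 snRNA, had 667 reads against 0, at least 1264-fold higher, and the 5S rRNA pseudogene RNA5SP208 had 763 against 0, at least 1446-fold higher. GAS5, a host transcript of snoRNAs (chromosome 1, 173863901 to 173869045), was 160-fold higher in diMARGI with 309 reads against 11 (88.0 to 323). In the opposite direction, HELLPAR, a very long non-coding RNA, had 2 reads in diMARGI against 700 in pxMARGI, 61.5-fold lower (17.0 to 509). HELLPAR did not pass the authors' threshold in pxMARGI.

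The 13 entries of the spliceosomal snRNA list with 50 reads in H9, RN7SK among them, were each higher in diMARGI, with a median log2 ratio of 9.61 at percentile 91.4 of matched random lists. With genes at 0 reads set to their bound, the median was 8.48. RNU12, the U12 snRNA of the minor spliceosome, had 241 reads against 1, and RNU4-1, a U4 snRNA, had 189 against 0, at least 358-fold higher. Of 7 cytoplasmic small RNA entries, 6 were higher in diMARGI, with a median of 11.72 at percentile 99.7, or 12.04 at the bound. The 5 entries of 7SK-type and RNase RNAs, which stand for 3 genes, were each higher, with a median of 9.13 at percentile 53.8, or 9.44 at the bound. That percentile ranks them among genes of like mean reads, many of which may be higher in diMARGI themselves. Among them RMRP, the RNA of RNase MRP (chromosome 9, 35657750 to 35658019), had 245 reads against 2, and RPPH1, the RNA of RNase P, had 177 against 2. Of 6 snoRNAs, 5 were higher in diMARGI at percentile 87.7, such as SNORD118, the U8 snoRNA, with 84 reads against 3, and SNORD14D with 130 against 0. SNORA7, with 0 reads against 102, was at least 5.98-fold lower. The 3 HOX antisense genes of the HEK293-type list had 0 diMARGI reads and 98, 65 and 60 in pxMARGI, HOXA-AS3 being at least 5.74-fold lower.

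Mitochondrial transcripts divided in H9, with 6 of 15 at 2-fold or more in diMARGI and 6 in pxMARGI, at percentile 36.0. MT-RNR2, the larger mitochondrial rRNA, was 31.1-fold higher in diMARGI (29.1 to 33.3) and MT-RNR1 was 71.3-fold higher (61.5 to 83.2). MT-TP was 2.41-fold higher in pxMARGI (1.64 to 3.68), a direction that turned under scaling by the expected count. Of 12 entries of the nuclear lncRNA list, 4 were higher in diMARGI and 5 in pxMARGI, at percentile 24.985, the 4 being RMRP and RPPH1 with 2 entries each. Without those, a choice made after seeing the data, 0 of 8 were higher in diMARGI, at percentile 59.3. KCNQ1OT1, an imprinted antisense RNA (chromosome 11, 2608328 to 2699994), had 7 reads in diMARGI against 490, 12.3-fold lower (5.93 to 30.8). SNHG14, a host of snoRNAs in the Prader-Willi region, had 44 reads against 277, and its ratio of 1.11 had an interval that held 1 (0.803 to 1.56). Of 6 snoRNA host genes, GAS5 and SNHG1 were higher in diMARGI, SNHG1 by 16.1-fold (11.5 to 22.9), and 2 others were 2-fold or more lower by ratio. Under TMM scaling, 4 host genes were lower in diMARGI. The median of the host genes, -0.61, stood at percentile 99.9 of matched random lists, or was -0.71 at the bound. SNHG16 and ZFAS1, with 7 and 6 diMARGI reads, had ratios of 1.66 and 1.61 in favour of pxMARGI with intervals that held 1.

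Over all 650 genes with 50 reads in H9, 84 were 4-fold higher in diMARGI and 532 were 4-fold higher in pxMARGI, 13.6% of calls being higher in diMARGI. The second count rests on the pseudocount of 0.5 reads. With genes at 0 reads set to the floor of 3 reads it was 276 (23.3% of calls higher in diMARGI), and 136 of these genes had a whole interval beyond 4-fold (38.2%), 2 alternatives chosen after seeing the data. Most calls were higher in diMARGI with a pseudocount of 5, at 84 and 70 genes (54.5%), and at a minimum of 200 reads, at 22 and 16 (57.9%). Scaling by the expected count raised every log2 ratio by 1.74 and gave 84 and 173 genes, 32.7% higher in diMARGI. The floor of H9 diMARGI, 6.97 per 100000, keeps the ratios of most genes higher in pxMARGI from being measured beyond a lower bound.

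In HEK, the same comparison asked the same question at greater depth. RNVU1-7 had 8182 reads in diMARGI and 0 in pxMARGI, at least 4190.3-fold higher, and RN7SL1 had 7257 against 0, at least 3717-fold higher. RN7SK, the 7SK RNA that restrains the transcription elongation factor P-TEFb (chromosome 6, 52995620 to 52995951), had 4663 reads against 1, a ratio of 7164 (95% interval 1285 to 283032). XIST, the RNA that coats the inactive X chromosome (chromosome X, 73820656 to 73852714), had 11720 reads against 165, 109-fold higher (93.6 to 128). MEG3, an imprinted lncRNA, had 0 reads in diMARGI and 155 in pxMARGI, at least 33.6-fold lower.

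The 17 entries of the spliceosomal snRNA list measured in HEK, RN7SK among them, were each higher in diMARGI, with a median log2 ratio of 8.81 at percentile 99.7 of matched random lists, or 9.02 with genes at 0 reads set to their bound. Of 81 snoRNAs, 78 were higher in diMARGI, with a median of 6.87 at percentile 100, or 5.83 at the bound, such as SNORD118 with 2838 reads against 0, at least 1453-fold, and SNORD43 with 775 against 0, at least 397-fold. The host genes of snoRNAs were higher too, 8 of 9 at 2-fold or more, with a median of 3.61 at percentile 78.2. Reads on a host gene may be those of the snoRNAs it carries, because the counting rule is unknown. The snoRNA and host gene lists are therefore not independent in any comparison. GAS5 was 131-fold higher (74.7 to 255), SNHG1 23.3-fold (18.4 to 29.9), SNHG12 13.0-fold (9.17 to 19.1) and SNHG3 12.3-fold (9.75 to 15.7). Of 9 cytoplasmic small RNA entries, 8 were higher in diMARGI, with a median of 10.93 at percentile 99.9, or 8.35 at the bound. The 5 entries of 7SK-type and RNase RNAs, again for 3 genes, were each higher, with a median of 12.22 at percentile 99.7, or 10.997 at the bound, RMRP with 3991 reads against 0 and RPPH1 with 3294 against 7.

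MT-RNR2 was 72.4-fold higher in HEK diMARGI (68.5 to 76.7) and MT-RNR1 94.7-fold higher (85.9 to 105), within a list of which 12 of 19 members were 2-fold or more higher in diMARGI and 5 in pxMARGI, at percentile 45.7. MT-TV reached 166-fold (103 to 285) and MT-TL1 51.3-fold (43.7 to 60.5). MT-TP was 2.55-fold higher in pxMARGI (2.15 to 3.04) and MT-TT 3.96-fold (3.19 to 4.95), directions that turned for MT-TP under TMM, median of ratios and expected-count scaling and for MT-TT under the last of these. Of 16 entries of the nuclear lncRNA list, 8 went each way, at percentile 65.2. Without the 2 entries each of RMRP and RPPH1, 4 of 12 were higher in diMARGI, the overlapping XIST and TSIX among them, and 8 in pxMARGI, at percentile 54.25. The 3 imprinted RNAs measured were lower in diMARGI, KCNQ1OT1 by 13.0-fold (9.18 to 18.9) with 34 reads against 677, and SNHG14 by 67.0-fold (18.3 to 557) with 2 against 206. Of the imprinted entries, 0 passed the authors' threshold in pxMARGI of either line. Their pxMARGI shares are therefore not an enrichment over the expected count. DUX4L26, a pseudogene of the DUX4 repeat family, had 2 reads against 1471, 479-fold lower (132 to 3957). The T cell receptor segment TRBV4-2 had 0 against 237, at least 51.4-fold lower, and the 3 HOX antisense genes on the HEK293-type list were lower too, such as HOXB-AS3 by 22.5-fold (9.47 to 70.2).

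Over the 1480 genes with 50 reads in HEK, 169 were 4-fold higher in diMARGI and 1271 in pxMARGI, 11.7% of calls being higher in diMARGI. With genes at 0 reads at the floor the counts were again 169 and 1271, and 165 and 1203 had a whole interval beyond 4-fold. At a minimum of 200 reads they were 66 and 45, most of them higher in diMARGI (59.5%). TMM, median of ratios and expected-count scaling raised every log2 ratio by 1.87, 1.97 and 2.79. Median of ratios gave factors of 0.25 in H9, 0.167 in HEK and 0.5 between the lines in diMARGI. These are ratios of small whole counts, so that scaling rests on genes with few reads. In all, 488 genes were called in both lines, of which 54 were higher in diMARGI and 431 higher in pxMARGI in both, and 3 went opposite ways. With genes at 0 reads at the floor these were 302, 54, 245 and 3.

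**Figure D2:**
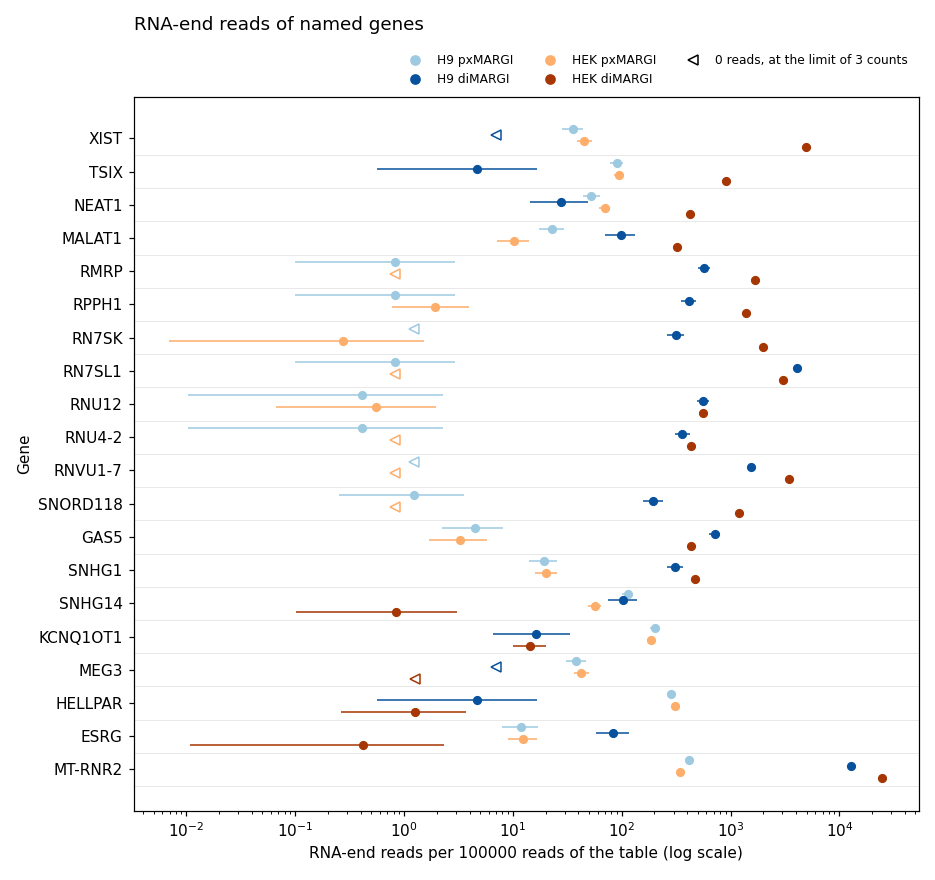
RNA-end reads per 100000 (log scale) for named genes in the 4 pooled tables, with exact 95% intervals and 0 counts drawn at the floor of 3 reads. XIST stood at 4945 per 100000 in HEK diMARGI and at 0 in H9 diMARGI, and MT-RNR2 at 24885 and 12888.

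H9 was set against HEK in pxMARGI to compare the lines within a protocol. Reads of most genes lay close to equal shares, with 985 of 1311 genes (75.1%) within 2-fold. RP11-265N6.2, an antisense gene, was 42.2-fold higher in H9 with 142 reads against 5 (95% interval 17.7 to 132), and SMAD1-AS1, antisense to the BMP signalling gene SMAD1, was 8.25-fold higher with 61 reads against 11 (4.30 to 17.4). NBPF8, of the neuroblastoma breakpoint family, was 19.2-fold higher in HEK with 200 reads against 7 (9.15 to 48.4), and LINC00640 19.8-fold with 59 against 2 (5.25 to 168). KCNQ1OT1 differed by 1.08-fold and TSIX by 1.05-fold, both with intervals that held 1.

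Of the lists in pxMARGI, 1 of 12 nuclear lncRNAs reached 2-fold between the lines, as did 1 of 6 snoRNA host genes, 1 of 4 snoRNAs and 3 of 16 mitochondrial transcripts, with medians at percentiles 27.1, 67.2, 80.0 and 13.1. NEAT1, the scaffold RNA of paraspeckles (chromosome 11, 65422798 to 65445540), was 1.32-fold higher in HEK (1.06 to 1.64), and SNHG14 was 2.00-fold higher in H9 (1.66 to 2.41). Among the mitochondrial transcripts, whose median was -0.25, MT-RNR2 was 1.204-fold higher in H9 (1.11 to 1.31), while MT-RNR1 was 1.48-fold (1.24 to 1.77), MT-TT 1.21-fold (1.05 to 1.38) and MT-TP 1.17-fold (1.03 to 1.33) higher in HEK. Of the HEK293-type HOX genes, HOXB-AS3 was 1.94-fold higher in HEK (1.44 to 2.65) while HOXA-AS3 was 1.55-fold higher in H9 (1.16 to 2.08). FBXL21 was 6.04-fold higher in H9 (3.46 to 11.2), AC027319.3 had 56 reads against 0, at least 27.8-fold, and the 7SK pseudogene RN7SKP297 had 1 read against 57, 38.3-fold lower (6.61 to 1539.9). Overall counts were 11 genes 4-fold higher in H9 and 37 in HEK, of which 3 and 5 had a whole interval beyond 4-fold. A pseudocount of 5 gave 7 and 16 genes, and with no minimum of reads 1471 and 1208 were called, most of them higher in H9 (54.9%). TMM, median of ratios and expected-count scaling shifted every log2 ratio by -0.03, -0.07 and -0.04. The sample descriptions and the table names disagree on the line, and the directions given here follow the table names.

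In diMARGI, H9 was set against HEK with depths of 43048 and 236995 reads. XIST had 0 reads in H9 and 11720 in HEK, at least 710-fold lower, and TSIX, which overlaps it on the other strand (chromosome X, 73792205 to 73829231), had 2 against 2162, 196-fold lower (95% interval 54.3 to 1622). The 2 cannot be separated without strand. NEAT1 was 15.1-fold higher in HEK with 12 reads against 1000 (8.63 to 29.4). RORB-AS1, antisense to the RORB gene, was 562-fold higher in H9 with 102 reads against 1 (98.5 to 22395), and the 5S rRNA pseudogene RNA5SP387 was 248-fold higher with 180 against 4 (95.1 to 919).

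The 8 nuclear lncRNA entries measured in diMARGI were each 2-fold or more higher in HEK, with a median log2 ratio of -1.75 at percentile 2.47, or -1.76 with XIST at its bound, and so were the 5 of 7SK-type and RNase RNAs, at percentile 6.63. RMRP and RPPH1, with 2 entries each, belong to both lists, and without them 4 of 4 nuclear lncRNA entries were higher in HEK, the overlapping XIST and TSIX among them, at percentile 0.02. Over all 197 genes the median was -0.999, with 93 genes 2-fold or more higher in HEK. RN7SK was 6.27-fold higher in HEK (5.29 to 7.50), RMRP 2.96-fold (2.60 to 3.38) and RPPH1 3.38-fold (2.91 to 3.95). Of 74 snoRNAs, 54 were higher in HEK and 2 in H9, at percentile 32.0, with SNORD43 8.80-fold (5.38 to 15.5) and SNORD118 6.14-fold (4.94 to 7.72) higher in HEK and SNORD14D 119-fold higher in H9 (53.3 to 331). Of 7 snoRNA host genes, 3 were higher in HEK and 0 in H9, at percentile 39.5, and more were higher in HEK under TMM scaling. Of 15 mitochondrial transcripts, 8 were higher in HEK, such as MT-TV at 5.74-fold (4.42 to 7.59), and 1 in H9, at percentile 18.3, whereas MT-RNR2 stood at 1.93-fold (1.88 to 1.99). Under TMM scaling, 15 mitochondrial transcripts were higher in HEK and 0 in H9.

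Of 15 spliceosomal snRNA entries, 5 were 2-fold or more higher in HEK, at percentile 43.0, RNVU1-7 at 2.23-fold (2.06 to 2.41), while under TMM scaling 15 were. Of 8 cytoplasmic small RNA entries, 2 were higher in H9 and 1 in HEK, at percentile 81.8, a balance that turned to 1 and 2 under TMM, and RN7SL1 was 1.34-fold higher in H9 (1.27 to 1.41). GAS5 was 1.66-fold higher in H9 (1.46 to 1.89), and both RN7SL1 and GAS5 turned to HEK under TMM, median of ratios and expected-count scaling. Of 20 measured entries of the rRNA class, 17 were 2-fold or more higher in H9, RNA5SP366 by 195-fold (74.7 to 727). Of the sense-overlapping and antisense genes, RP3-428L16.2 had 263 reads in H9 against 5 and RP11-298J20.4 had 89 against 1.

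Over 197 genes with 50 reads in diMARGI, 37 were 4-fold higher in H9 and 51 in HEK, 42.0% of calls being higher in H9, and 51 genes (25.9%) lay within 2-fold. With genes at 0 reads at the floor the counts were 37 and 49, and 35 and 16 had a whole interval beyond 4-fold (68.6% higher in H9). Most calls were likewise higher in H9 with a pseudocount of 5, at 37 and 18 (67.3%), at a minimum of 10 reads, at 126 and 81 (60.9%), and with no minimum, at 420 and 81 (83.8%). TMM scaling, which lowered every log2 ratio by 1.32, gave 30 and 111 genes (21.3% higher in H9), median of ratios 30 and 117 (20.4%), and the expected count 31 and 104 (23.0%). Tables were assigned to lines by their names, since all 5 H9 samples and 5 of the 6 pooled HEK samples name a table of the other line in their descriptions. The pluripotency list was 106-fold higher in the diMARGI table named H9 (34.7 to 531), while its ratio in pxMARGI was 1.10 (0.787 to 1.52), which leaves the lines of those tables to their names.

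**Figure D3:**
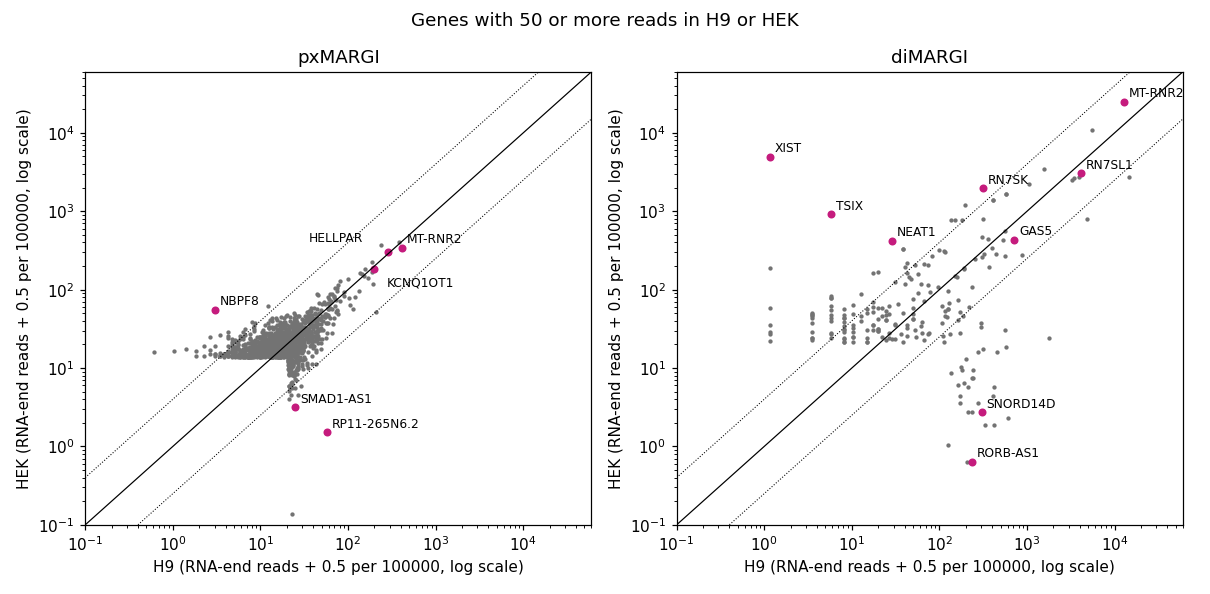
RNA-end reads plus 0.5 per 100000 in H9 (horizontal) and HEK (vertical) for each gene with at least 50 reads in either line, pxMARGI left and diMARGI right, on log axes, with the line of equality solid and 4-fold bounds dotted. Of genes with 50 reads in the line where they were higher, 75.1% of 1311 in pxMARGI and 25.9% of 197 in diMARGI lay within 2-fold. Some plotted genes fall outside that set. The straight lower edges of the pxMARGI cloud come from the minimum of 50 reads.

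Several lists had few or 0 members among these non-coding genes. The 21 histone entries, mostly pseudogenes, had 86 and 156 reads in H9 and HEK pxMARGI and 1 and 2 in diMARGI, with 0 members at 50 reads. The ribosomal protein list matched 1 entry, the pseudogene RPS10L, with 8 and 1 reads in H9 and HEK pxMARGI and 0 in both diMARGI tables. Housekeeping mRNAs and early lineage genes matched 0 entries. The 7 pluripotency entries had 0 members at 50 reads in any table.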

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

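All tests in this part were chosen only after the results they bear on had been seen. The XIST and TSIX genes moved in opposite directions between the protocols in the 2 lines. The log2 ratio of diMARGI over pxMARGI was -4.94 in H9, where XIST had 0 diMARGI reads and was at least 5.10-fold lower, and 6.77 in HEK for XIST, and -3.96 and 3.27 for TSIX. Neither XIST nor TSIX passed the authors' threshold in pxMARGI of either line. MT-TW, a mitochondrial tRNA gene, likewise stood at -2.41 in H9 and 2.27 in HEK. The H9 value of MT-TW rests on 2 diMARGI reads against 75 in pxMARGI. Scaling by the expected count, which raised every H9 log2 ratio by 1.74, leaves MT-TW short of 4-fold. The same shift takes the H9 bound of 5.10-fold for XIST below 4-fold. The difference between the lines was not tested for any of the 3 genes, since each value compares 1 pool with another.

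For XIST, low depth in H9 diMARGI is argued against by the 2129 reads expected there at the HEK share, where 0 were seen. Loss of the locus in H9 is argued against by the pxMARGI DNA ends at XIST, whose share in H9 was 0.674 of that in HEK (95% interval 0.517 to 0.872). TSIX may be counting reads of the overlapping XIST, because its diMARGI share in H9 was 0.00509 of that in HEK (0.000616 to 0.0184) and so followed XIST. A difference between the cell lines, which the design names, stays open as an untested biological explanation. An exchange of the lines between the diMARGI tables is argued against by the pluripotency list, fixed before the data were examined, which was 106 times higher in the table named H9 (34.7 to 531).

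Among DNA ends, which the comparisons did not use, processed pseudogenes took 60.6% in H9 diMARGI and 54.8% in HEK diMARGI, against 20.3% and 21.2% in pxMARGI. RPL4P4, a pseudogene of a ribosomal protein gene (chromosome 3, 185417408 to 185418843), had 368 DNA ends in H9 diMARGI and 12 in H9 pxMARGI, and RPL13P12 had 1050 in HEK diMARGI and 16 in HEK pxMARGI. Copies in general being hard to place stays open, because relative to lincRNA and antisense DNA ends, unprocessed and other pseudogenes rose from pxMARGI to diMARGI as well, 1.75 times in H9 (1.64 to 1.87) and 1.30 times in HEK (1.26 to 1.35), against 27.4 and 11.6 times for processed pseudogenes. Sequence from mRNA or cDNA read as DNA ends is a candidate explanation, since ribosomal protein pseudogenes, copies of abundant mRNAs, took 1.85 times their pxMARGI share of processed pseudogene DNA ends in H9 (1.77 to 1.94) and 3.24 times in HEK. No biological explanation was tested.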

How the results depend on the processing

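Scaling by the recovered expected count, leaving out repeated entries, setting genes at 0 reads to the floor, asking for a whole interval beyond 4-fold and taking RMRP and RPPH1 out of the nuclear lncRNA list were chosen after seeing the data. No paired analysis was possible because each group is a single pooled table, and for the same reason no replicate could be left out. A comparison of protein-coding genes alone was not run, since 0 are listed, and alternatives for files without counts were not needed. Of 274 counts, shares and correlations under the alternatives, 163 stayed within 1.5 times or their interval and 111 moved. Counts of genes moved with the minimum by construction, since other genes enter. In H9, diMARGI and pxMARGI had 84 and 532 genes at 50 reads, 231 and 2237 at 10, 583 and 2237 with no minimum and 22 and 16 at 200. HEK diMARGI and pxMARGI had 445 and 9225, 610 and 10837, and 66 and 45. The lines H9 and HEK had 635 and 996, 1471 and 1208, and 1 and 2 in pxMARGI, and 126 and 81, 420 and 81, and 6 and 17 in diMARGI. A pseudocount of 5, which pulls low counts together, left 70 genes higher in H9 pxMARGI, 7 and 16 between the lines in pxMARGI and 18 higher in HEK diMARGI. Genes at 0 reads set to the floor left 276 higher in H9 pxMARGI, and a whole interval beyond 4-fold, a stricter rule, left 136 there, 3 and 5 between the lines in pxMARGI and 16 higher in HEK diMARGI. A 2-fold threshold gave 92 and 234 in pxMARGI and 93 higher in HEK diMARGI. Genes higher in HEK diMARGI numbered 111 under TMM, 117 under median of ratios and 104 under the expected count, and genes higher in H9 pxMARGI 173 under the expected count, each from a shift of every ratio. Members of any list, at 10 reads, numbered 87 and 52 in H9 diMARGI and pxMARGI, 267 and 69 in HEK, 25 and 21 for the lines in pxMARGI and 21 and 132 in diMARGI, where TMM gave 2 and 119. Per list, 11 of 48 counts moved under TMM and 21 of 48 at a minimum of 10 reads. Without RMRP and RPPH1, nuclear lncRNAs numbered 0 higher in H9 diMARGI and 4 in HEK diMARGI against pxMARGI, and 4 higher in HEK diMARGI against H9, fewer entries being counted. Under TMM, snoRNA host genes higher in H9 pxMARGI numbered 4, and in HEK pxMARGI host genes 0, mitochondrial transcripts 3 and cytoplasmic small RNAs 0. For the lines in diMARGI, TMM gave 15 snRNAs, 6 host genes, 15 mitochondrial transcripts and 2 cytoplasmic small RNAs higher in HEK, and 1 snoRNA, 0 mitochondrial transcripts and 1 cytoplasmic small RNA in H9. At 10 reads, H9 pxMARGI had 16 nuclear lncRNAs, 8 host genes and 9 snoRNAs, and H9 diMARGI 5 host genes and 41 snoRNAs. HEK pxMARGI had 22 nuclear lncRNAs, 3 host genes and 21 snoRNAs and HEK diMARGI 203 snoRNAs. Between the lines in pxMARGI, H9 had 3 nuclear lncRNAs, 5 host genes and 3 mitochondrial transcripts and HEK 2 nuclear lncRNAs and 1 host gene. In diMARGI, H9 had 2 nuclear lncRNAs, 10 snoRNAs and 2 mitochondrial transcripts and HEK 8 snRNAs, 7 host genes, 98 snoRNAs and 2 cytoplasmic small RNAs. The stricter q-value of 0.001 left 2424 genes in H9 pxMARGI and 3604 in HEK pxMARGI. Among genes with 50 reads in both tables, shared calls numbered 370 (331 for independent lists) between the pxMARGI tables, 56 (56) between the diMARGI tables, 4 between the H9 tables, 25 between the HEK tables, 17 for H9 pxMARGI with HEK diMARGI and 6 for H9 diMARGI with HEK pxMARGI, fewer genes being compared, and outside the pxMARGI pair each number equalled that for independent lists. With the smaller totals left by removing mitochondrial and ribosomal RNA, lincRNA and antisense took 49.9%, 14.2%, 48.3% and 22.7% in H9 pxMARGI, H9 diMARGI, HEK pxMARGI and HEK diMARGI, and snRNA, snoRNA and scaRNA 16.8% and 27.8% in H9 and HEK diMARGI. Without the 10 largest genes these were 49.9%, 22.6%, 48.4% and 20.9%, and 26.7% and 32.3%. At 50 reads in either table the Spearman rho was 0.430 between the pxMARGI tables, 0.206 between the diMARGI tables, -0.245 between the H9 tables, -0.186 between the HEK tables, -0.437 for H9 pxMARGI with HEK diMARGI and -0.0950 for H9 diMARGI with HEK pxMARGI; the cause was not tested. Of 182 ratios of named genes, TMM kept 122 within their interval, median of ratios 122, the expected count 115, a pseudocount of 5 124, totals without mitochondrial and ribosomal RNA 154 and totals without the largest genes 150. Of ratios whose interval left out 1, those reversed were DBET and MT-TP in H9 protocols under the expected count, at log2 0.24 and 0.50, and in HEK MT-TP under TMM, median of ratios and the expected count, at 0.52, 0.62 and 1.45, and MT-TT under the expected count, at 0.81, each from the shift of every ratio. So were, for H9 against HEK in diMARGI, under TMM, median of ratios and the expected count, GAS5 at -0.59, -0.73 and -0.35, both RN7SL1 entries at -0.90, -1.04 and -0.67, Metazoa_SRP at -0.95, -1.08 and -0.71, and RN7SL2 at -0.91, -1.05 and -0.67. The floor of 3 reads was 6.97 per 100000 in H9 diMARGI against 1.23, 0.824 and 1.27 in H9 pxMARGI, HEK pxMARGI and HEK diMARGI, and lower values were not measured.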

Other observations

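All tests in this part were chosen only after the results had been seen, and a narrower test of short RNAs was added after the first left the matter open. The gene lists were fixed before the data were examined, while MIR302C, MIR302D, MIR92A1, ESRG and LINC00678 were picked out after their values were seen. The 7 pluripotency entries together had 135 reads per 100000 in H9 diMARGI (95% interval 102 to 174) and 1.27 in HEK diMARGI, against 27.4 and 24.99 in H9 and HEK pxMARGI. ESRG, a transcript of human embryonic stem cells (chromosome 3, 54632124 to 54639857), had 36 reads in H9 diMARGI and 1 in HEK diMARGI, and LINC00678 had 16 and 0. MIR302C and MIR302D, of a microRNA cluster active in pluripotent cells, had 10 and 9 reads in H9 diMARGI and 0 in HEK diMARGI. MIR92A1, of the miR-17-92 cluster, had 74 reads in H9 diMARGI and 10 in HEK diMARGI.

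The 15 imprinted non-coding RNA entries had 197 reads per 100000 in H9 diMARGI (158 to 244) and 17.7 in HEK diMARGI (12.8 to 24.0), against 405 and 319 in pxMARGI. In reads these were 85 in H9 diMARGI, 44 of them on SNHG14, and 42 in HEK diMARGI, 2 of them on SNHG14. The 6 HEK293-type entries had 104 and 108 reads per 100000 in H9 and HEK pxMARGI, 0 in H9 diMARGI and 4.64 in HEK diMARGI.

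The 30482 genes with a recovered expected count leave out mitochondrial rRNA and genes such as RNVU1-7, and hold 7 of the 22 mitochondrial tRNAs. A gene entered only with reads and a p-value within the limits in some table, and RNA ends fell on more genes in pxMARGI. Summed over these genes, the RNA ends were 1.11 and 1.14 times the expected count in H9 and HEK pxMARGI, against 2.48 and 4.53 in diMARGI. Single genes departed far from their expected count, DUX4L26 being at 113 and 122 times its own in H9 and HEK pxMARGI. DUX4L26 also had 683 and 1245 DNA ends there, beside 944 and 1471 RNA ends. In H9 and HEK pxMARGI, 10.2% and 13.8% of all genes passed the authors' threshold. The sum therefore does not describe each gene. Over the same genes, the Spearman rho of RNA ends with the expected count was 0.615 and 0.568 in H9 and HEK pxMARGI and -0.00166 and 0.0648 in diMARGI. The choice of genes favours those near their expected count in pxMARGI, so part of that difference between the protocols may follow from it. A minimum of 10 reads at either end, which also selects on the reads, gave 0.518 and 0.501 in pxMARGI and -0.390 and -0.412 over 845 and 1432 genes in diMARGI. Loss of short RNAs alone was examined in 13 genes with a RefSeq span of 1000 bp or more, such as XIST and SNHG1. Each had at least 50 reads and over 10 times the expected count in HEK diMARGI. Relative to all genes, their level over the expected count in HEK pxMARGI was at most 0.242 of that in HEK diMARGI (0.163 to 0.356). The span is not the length of the RNA, and reads on host genes such as SNHG1 may be those of snoRNAs. The genes were also chosen by their diMARGI excess, so the test does not decide the explanation. Genes of that span with a smaller excess were not part of the test. Whether the 13 genes exceed the expected count in pxMARGI at all stays open, with a median of 1.08 and quartiles from 0.860 to 2.03. Whether pxMARGI follows RNA level stays open too: genes higher in H9 and genes higher in HEK diMARGI differed by a ratio of 1.26 in pxMARGI (1.03 to 1.55), over 88 genes. Genomic DNA read as RNA ends is a candidate explanation, since immunoglobulin and T cell receptor segments, which are transcribed in lymphocytes, reached 1.32 times the level of all genes over their expected count in H9 pxMARGI (1.25 to 1.39), against 0 in H9 diMARGI and 0.00503 in HEK diMARGI. Only 389 of 640 segments had an expected count, which required reads, and these came nearly all from pxMARGI. That filter can raise the pxMARGI value, which therefore does not decide the explanation. Over all 640 segments, RNA ends were 1873 and 3045 in H9 and HEK pxMARGI and 0 and 3 in diMARGI. Passive contacts, which the design names, were not tested.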
